A study of Oryza sativa with 6 samples.

How the data were processed

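The series holds 6 two-colour Agilent oligonucleotide arrays of total RNA from developing rice caryopses, at high temperature and in a control, with 400 ng of each RNA labelled with Cy3 or Cy5 per the labels' protocols. Each of 3 biological replicates was hybridised to 2 arrays with the dyes exchanged, and no common reference was used. The direction of every ratio was taken from the dye labels of the 2 channels. Replicates were said by the labels to be biologically independent. Replicates 1 and 2 were on 1 slide and replicate 3 on another.

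Per the file headers, the spot and local background intensity values deposited by the authors were measured with Agilent Feature Extraction 9.5.3.1, while the submitters' processing notes give version 9.1. The deposited processed intensity values were background-subtracted, spatially detrended and dye-normalized by that software per the file headers, with surrogate values in place of low signals at 19.3% to 21.6% of spots. The deposited log10 ratio is red over green processed signal per the file headers, which held within 0.0005 for 100% of the spots without a surrogate. The software's deposited p-value of each log ratio was not used here. The multiplier that defines a spot as well above background was 2.6 on slide 1 and 13 on slide 2, and multiplicative detrending was on for slide 2 only, per the file headers. The deposited series matrix holds log10 ratios equal, within 4.92e-06, to those of the scanner files turned to high temperature over control on all 6 arrays, with a median of 0 in each. Its scale, direction and centring are therefore known. Array-wide median intensity was 646 to 722 in Cy5 and 356 to 402 in Cy3, against local background of 54 to 56 and 48.5 to 51.5. There were 14 to 250 outlier spots on an array, fewest on slide 2, and 1 saturated spot in all.

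From these values, mean signals were corrected for local median background by normexp with an offset of 50 and normalized within each array by loess, with control and outlier spots at weight 0. Outlier spots were left out afterwards. Spots of one probe sequence were averaged, the sign was turned to high temperature over control, and the 2 arrays of a replicate were averaged, because they carry the same 2 RNAs. The array holds 42105 spots naming a locus, with 37449 probe sequences of 60 bases for 29689 loci, and 268 sequences are listed under several loci. A probe was tested when it was well above background on all 6 arrays in at least 1 condition and had at least 2 complete replicates; 137 of the tested probes had only 2. An intercept model with empirical Bayes moderation was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), and p-values were adjusted by the Benjamini-Hochberg method over all tested probes at a threshold of 0.05. The brightest tested probe stood for each gene. Of 5001 genes with several tested probes, 180 had probes called in opposite directions.

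A gene that was not well above background on any array of a condition is given as "at least N-fold": the bright condition's mean against the dim condition's mean of, per array, the higher of the lowest signal well above background and the probe's own signal, per channel after loess and Aquantile. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 23 lists, with camera at an estimated correlation and with fry as alternatives. With 3 replicates, camera at an estimated correlation has few degrees of freedom and little power, so a list that fails it is not thereby shown unchanged. Fry asks whether the genes of a list move on balance one way, without comparing them with other genes.

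Named genes followed a rule fixed in advance: the 10 largest rises and 10 largest falls among annotated genes past the threshold with 1 sign on all 6 arrays, up to 4 called members of each list with the largest absolute ratio, and 28 genes of starch, storage protein and heat response whatever their values. This named 122 tested genes and 3 that were not tested, and the text gives a selection of them. In the lists, 1 locus was dropped because its description names another protein and 1 was not on the array. Gene names and descriptions are those of the array's design. None of the 29689 loci matched the reference gene table, so no coordinates are given; the 2 digits after "Os" in a locus name are its chromosome. The probe names give the coding sequence and 3' untranslated region as the target for 15598 of the 21140 tested genes.

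The alternatives were no background correction, the processed signals, the series matrix, median centring, scaling between arrays, a normexp offset of 16, no filter and a stricter filter, the 6 arrays with the replicate as a random block or with a dye coefficient, each dye orientation alone, separate channels with and without a replicate block, the slide as a block, each replicate left out, a variance trend, and for lists the mean over a gene's probes. The groups, tests, gene lists, naming rule and these alternatives were fixed before the data were examined. Centring on the spike-in probes was added after seeing the data. Its p-values are not sound, because a shift shared by all probes made the prior degrees of freedom infinite, and ranges over alternatives leave it out.

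The steps were tested on simulated data made from these arrays, with 200 changed probes among the 27822 tested. For the comparison of high temperature with control, 20% of 50 probes changed 1.25-fold were called. The share called was 94% at 1.5-fold, 100% at 2-fold and 100% at 4-fold. Of 27592 unchanged probes, 21 were called. The calls numbered 203 in all, so a larger share of them was false than the adjusted p threshold allows on average. A list shifted by 0.5 was called and 0 of the other simulated lists were. The noise was drawn independently for each probe and the simulated lists were random genes, so lists of correlated genes were not tested. In the data the estimated correlation within a list reached 0.765, for ribosomal proteins. The simulation also held far fewer changed probes than the data, where 46.8% of tested probes passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.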

Results

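Transcript levels were compared between developing rice caryopses, the grains that form from the fertilised ovary, filling at high temperature and at a control temperature. Plants of the japonica cultivar Nipponbare grew at 27 °C by day and 22 °C by night until flowering. At 5 days after flowering they were moved either to 33 °C by day and 28 °C by night or to 25 °C by day and 20 °C by night. Caryopses were taken 10 days after flowering at high temperature and 12 days after flowering in the control, so the age at harvest differed together with the temperature. Each RNA came from 12 caryopses, and each condition had 3 biologically independent replicates. Each pair of RNAs was hybridised to 2 arrays with the dyes swapped, which gave 6 arrays. Between 74.8% and 80.8% of the spots of an array channel were well above background. Per the file headers, the log ratios that Feature Extraction gave for the spike-ins of known ratio had a slope of 0.899 to 0.915 on each array. That slope was not computed for the 10 spike-in probes with the ratios used here, which were normalized otherwise. The number of replicates limits the precision of every value below. Ratios are log2 of high temperature over control, as mean ± SD over n = 3 replicates, with the same sign on all 6 arrays unless stated otherwise. Adjusted p-values are from limma over all tested probes.

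The comparison asks which transcripts of the filling grain differed between high and control temperature. Among annotated genes that passed with 1 sign on all 6 arrays, the thionin gene Os06g0514100 rose most, by 4.61 ± 0.53 (24.4-fold, adjusted p = 0.000784). It encodes a small cysteine-rich defence protein. Of 22 small heat shock protein genes 14 rose, 2 fell and 6 did not pass. For the list, camera gave an adjusted p of 0.0016 with the preset correlation and 0.936 with an estimated correlation. Os04g0445100, annotated as a class IV heat shock protein but in none of the lists fixed in advance, rose by 3.15 ± 0.34 (adjusted p = 0.000784). The gene for granule-bound starch synthase I (Waxy), which makes amylose, fell by 1.26 ± 0.19 on the log2 scale (adjusted p = 0.00108), and 9 of 13 prolamin genes, which encode alcohol-soluble storage proteins, fell. Of 47 histone genes 21 fell, 3 rose and 23 did not pass. Camera gave adjusted p-values of 0.043 for prolamins and 0.00428 for the list of cell cycle and histone genes with the preset correlation. With an estimated correlation the adjusted p was 0.936 for each of these lists. Among the histones Os05g0461400, for a histone H2A, was at -0.998 ± 0.15 (adjusted p = 0.00121). The largest fall among annotated genes with 1 sign on all 6 arrays was that of Os04g0662600, at -2.92 ± 0.53 (adjusted p = 0.00108). It is annotated as flavanone-3-hydroxylase, a flavonoid pathway enzyme.

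Of 27822 probes tested, for 21140 loci, 13020 passed an adjusted p of 0.05, 6709 of them higher and 6311 lower at high temperature. The median absolute log2 ratio of these probes was 0.36, and 580 probes differed at least 2-fold, 363 higher and 217 lower. With the processed signals or the series matrix 1196 did so (720 higher and 476 lower). In the simulated data 2-fold changes came back at a median of 1.91-fold with the main steps, so the count of 580 may be low. With 1 probe per gene, 5057 genes were higher and 4789 lower. When the ratios were instead centred on the spike-in probes, a setting chosen after seeing the data, 9035 probes passed and 34.8% of these were higher, against 51.5% with the main centring. Each replicate's spike-in shift is shared by all probes, which made limma's prior degrees of freedom infinite there, so that count is not a sound test and is given only for the split. The shift was -0.056, 0.255 and 0.061 in replicates 1, 2 and 3 (0.086 ± 0.157). The split thus rests on a shift that is not told apart from 0. Log2 ratios of replicates 1 and 2, 1 and 3, and 2 and 3 correlated across probes with r of 0.76, 0.87 and 0.85 (probes are not independent replicates). Replicates 1 and 2 shared a slide and replicate 3 was on another. With the slide as a block 7573 probes passed, 4020 higher and 3553 lower, and on slide 1 alone, which is the fit without replicate 3, 5008 passed. Slide 2 holds 1 replicate and gives no test; across probes the mean log2 ratio of slide 1 and the log2 ratio of slide 2 correlated with r = 0.919 (again, probes are not independent).

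Other genes with large rises included Os06g0514800, annotated as the thionin-type toxin phoratoxin, at 4.13 ± 0.59, and a further thionin gene, Os06g0512700, at 3.48 ± 0.77. Os08g0518900, for a family 18 glycoside hydrolase, rose by 3.50 ± 0.34, with 1.66 as the lowest value among its 3 probes. Os04g0352400, an FKBP12-type immunophilin of the peptidyl-prolyl isomerase family, rose by 2.96 ± 0.02. A BURP domain gene, Os10g0409400, rose by 2.93 ± 0.38. The brightest probe of Os03g0701100, annotated as the splicing factor PRP18, was at 4.15 ± 0.29, whereas another of its 3 probes was at 0.44, so the size of its change depends on the probe. Among the falls were a gene for 1-aminocyclopropane-1-carboxylate oxidase, the last step of ethylene synthesis (Os09g0451000, -2.23 ± 0.17, its 3 probes running from -2.23 to -1.11), and a class III chitinase gene (Os10g0416800, -2.21 ± 0.57). Os02g0740400, for a lipolytic enzyme of the GDSL family, was at -2.27 ± 0.20 (other probe -1.78), and the Piwi domain gene Os02g0616300 at -2.20 ± 0.21. The tonoplast aquaporin gene TIP2.1 (Os02g0658100) was at least 3.64-fold lower by its brightest probe (adjusted p = 0.000788; its other probe was at -1.76) and the O-methyltransferase gene Os10g0118200 at least 3.83-fold lower (adjusted p = 0.000801), both being not well above background at high temperature on any array. Os10g0208800, for a BED finger protein, averaged -2.66 ± 2.08 (adjusted p = 0.0347), with -4.52, -3.05 and -0.41 in replicates 1, 2 and 3. It did not pass without replicate 1 (adjusted p = 0.0781) or without replicate 2 (0.0746), and its adjusted p ranged from 0.00495 to 0.0781 over the alternatives set in advance.

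**Figure D1:**
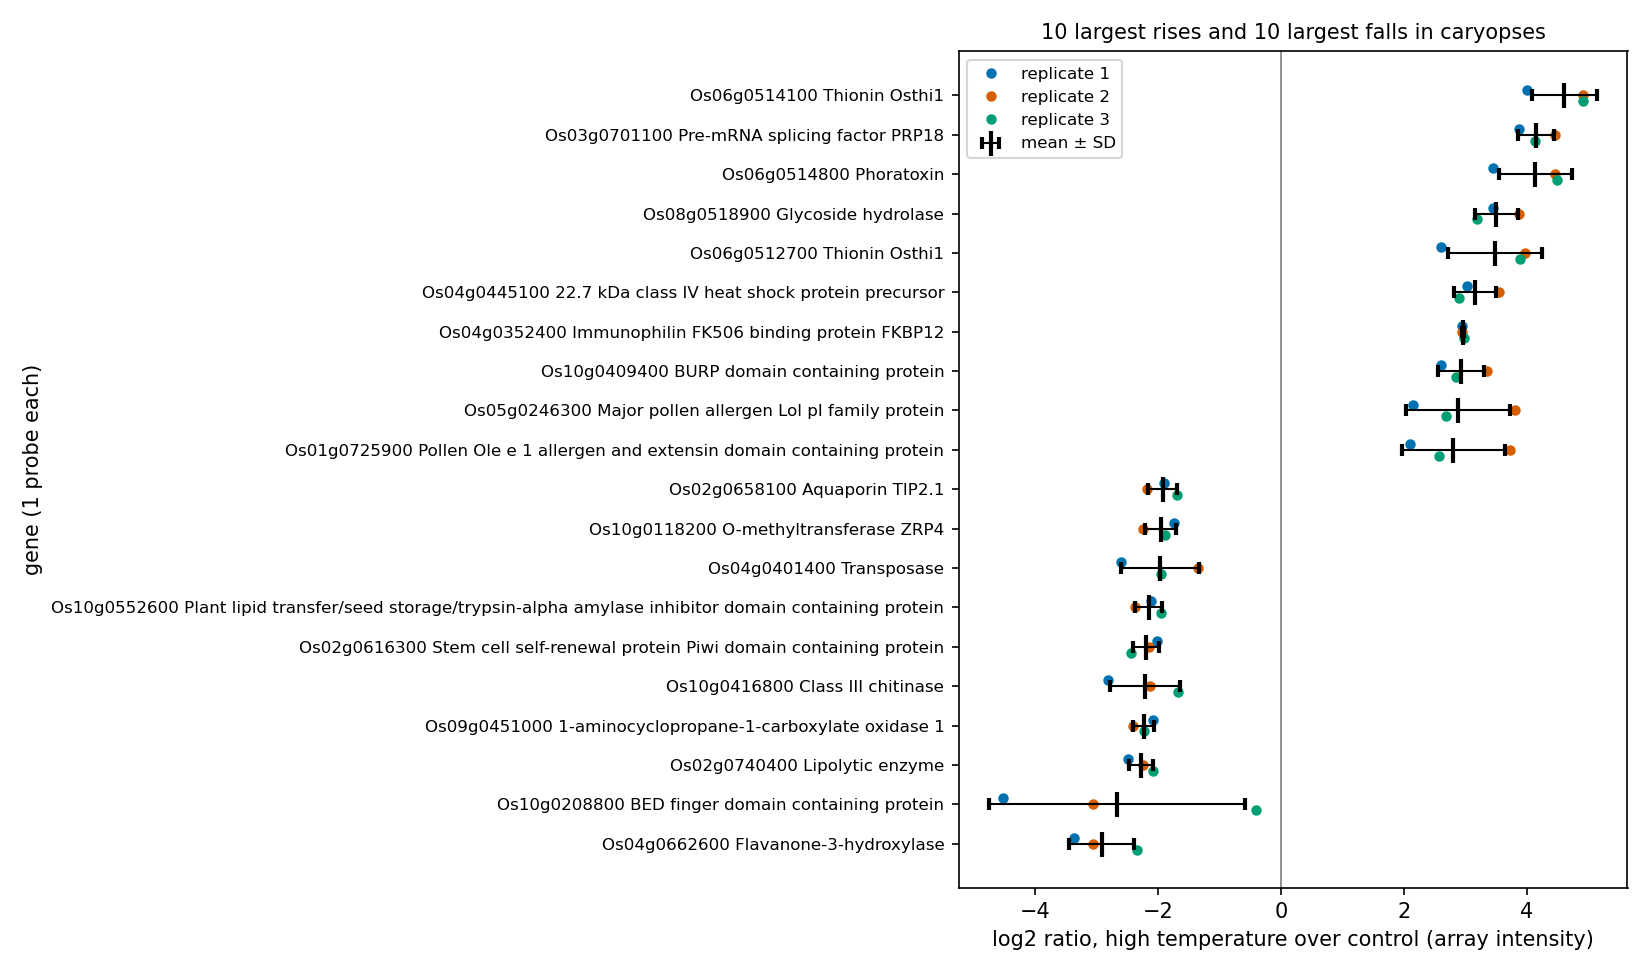
Log2 ratio of high temperature over control for the 10 largest rises and 10 largest falls among annotated genes with the same sign on all 6 arrays. Coloured points are the 3 replicates, each the mean of 2 dye-swapped arrays, and black marks with bars are mean ± SD; the rises reach 4.61 for Os06g0514100 and the falls -2.92 for Os04g0662600, and the replicates of Os10g0208800 lie farthest apart.

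Small heat shock proteins are chaperones that hold unfolded proteins, and of the 22 measured genes 17 rose and 3 fell when adjusted over the list alone. The list's median was 0.37, and camera with a preset correlation of 0.01 gave an adjusted p of 0.0016 over 23 lists, while adjusted p = 0.936 with an estimated correlation between genes; with the slide as a block it was 0.00179, and over the alternatives set in advance 1.75e-10 to 0.936. Os02g0758000 rose by 2.69 ± 0.28 (lowest of its 3 probes 1.38), HSP26 (Os03g0245800) by 2.25 ± 0.04 (n = 2 replicates, 5 of 5 measured arrays) and Os03g0266300, an Hsp20 gene, by 1.60 ± 0.27 (lowest of its 4 probes 1.08). The list's median was 0.34 on slide 1 and 0.37 on slide 2. Of 110 genes for larger heat shock proteins and chaperones 42 rose, 15 fell and 53 did not pass (44 rose and 17 fell adjusted over the list alone), with a list adjusted p of 0.10. HSP101 (Os05g0519700), the ClpB-type disaggregase, rose by 1.07 ± 0.21 (adjusted p = 0.00148) and HSP70-2 (Os11g0703900) by 1.59 ± 0.07, with 0.47 as the lowest value among its 4 probes. The brightest HSP90 probe (Os04g0107900) was at 2.68 ± 0.53 and the lowest of its 4 probes at 0.26. The DnaJ gene Os02g0656500 fell by 1.37 ± 0.02, and its other probe was at -0.77. Heat shock transcription factors went both ways, with 6 of 21 higher, 4 lower and 11 not passing, the same 6 and 4 adjusted over the list alone, and a list adjusted p of 0.461. The brightest probe of HsfA2a (Os03g0745000) was at 1.00 ± 0.24 and the lowest of its 3 probes at 0.17, while Os06g0553100, annotated as heat shock factor 29, fell by 1.87 ± 0.16. HsfA2c (Os10g0419300) was at -0.29 ± 0.07 (adjusted p = 0.0111), a call that was lost without replicate 3 (adjusted p = 0.0581) and with the slide as a block (0.0531), in a range over the alternatives of 0.00107 to 0.0581.

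Of 16 genes for protein folding in the endoplasmic reticulum 7 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone and a list adjusted p of 0.0914. The calreticulin genes moved apart, with Os03g0832200 at 1.22 ± 0.11, Os01g0895600 at 0.86 ± 0.11 and Os05g0507300 at -1.08 ± 0.24. ERO1 (Os03g0733800), which oxidises protein disulfide isomerase, rose by 0.53 ± 0.17. BiP1 (Os02g0115900), the luminal HSP70, was at 0.10 ± 0.29 (adjusted p = 0.506, positive on 4 of 6 arrays) and PDIL1-1 (Os11g0199200), a disulfide isomerase, at -0.10 ± 0.07 (adjusted p = 0.206, negative on 3 of 6 arrays). Over the alternatives set in advance the adjusted p of PDIL1-1 ranged from 0.0108 to 0.608, so its call depends on the setting.

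Starch synthesis genes mostly fell where they passed. Of 24 measured genes 3 rose, 10 fell and 11 did not pass, with 3 and 10 also adjusted over the list alone, and a list adjusted p of 0.453. After Waxy (Os06g0133000), the largest fall was that of BEIIb (Os02g0528200), a starch branching enzyme of the endosperm, at -0.82 ± 0.12 (adjusted p = 0.00142; other probe -0.54). The ADP-glucose transporter gene BT1-1 (Os02g0202400) fell by 0.51 ± 0.16 and the debranching enzyme gene ISA1 (Os08g0520900) by 0.43 ± 0.21. Smaller falls were those of AGPS2 (-0.32 ± 0.15), AGPL2 (-0.20 ± 0.10), SSIIa (-0.34 ± 0.18) and PHO1 (-0.34 ± 0.22), none of which held in all fits that left out 1 replicate. AGPS2 was lost without replicate 3 (adjusted p = 0.0749), AGPL2 without replicate 1 (0.158), 2 (0.0732) or 3 (0.122), SSIIa without replicate 1 (0.0637) and PHO1 without replicate 1 (0.0987) or 2 (0.0820). With the slide as a block they were at 0.0707, 0.143, 0.0547 and 0.0556 in the order AGPS2, AGPL2, SSIIa and PHO1. The lowest and highest adjusted p over the alternatives set in advance were 0.0071 and 0.0829 for AGPS2, 0.0121 and 0.158 for AGPL2, 0.00324 and 0.0637 for SSIIa, and 0.00496 and 0.0987 for PHO1. Other probes of AGPS2 and AGPL2 reached 0.12 and 0.06. SSI (Os06g0160700), for a soluble starch synthase, rose by 0.71 ± 0.27 (adjusted p = 0.00619). The pullulanase gene PUL was at 0.21 ± 0.09 (adjusted p = 0.0349), a call lost without replicate 2 (0.0849), without replicate 3 (0.206) and with the slide as a block (0.0852), in a range over the alternatives of 0.0124 to 0.206.

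Among 11 starch degradation genes 2 rose, 4 fell and 5 did not pass, and adjusted over the list alone 2 rose and 5 fell. The rises were those of the alpha-amylase genes RAmy3E (Os08g0473600), at 1.43 ± 0.17 (adjusted p = 0.000835), and Os02g0765300, at 1.15 ± 0.09. The list's median was -0.09, its mean 0.15 and its adjusted p 0.931. RAmy1A was not well above background on any array, and no probe of RAmy3D was so on more than 5 of 6 arrays at high temperature or 4 of 6 in the control. RISBZ1, a regulator of storage protein genes, had 1 complete replicate after outlier spots were left out, and these 3 genes were not tested. Of 43 genes for sucrose import and cleavage 3 rose, 11 fell and 29 did not pass (2 and 7 adjusted over the list alone; list adjusted p of 0.459). SUT1 (Os03g0170900), a sucrose transporter, fell by 0.50 ± 0.06 (the weakest of its 4 probes was at -0.27), while the hexokinase gene Os01g0742500 rose by 0.96 ± 0.13. The brightest probe of the sucrose synthase gene SUS2 (Os06g0194900) was at -0.47 ± 0.02 and another of its 6 probes at 0.30. SUS3 was at 0.17 ± 0.62 (adjusted p = 0.565, positive on 4 of 6 arrays), and at 0.53 without replicate 2 (adjusted p = 0.00368, in a range over the alternatives of 0.00368 to 0.99).

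**Figure D2:**
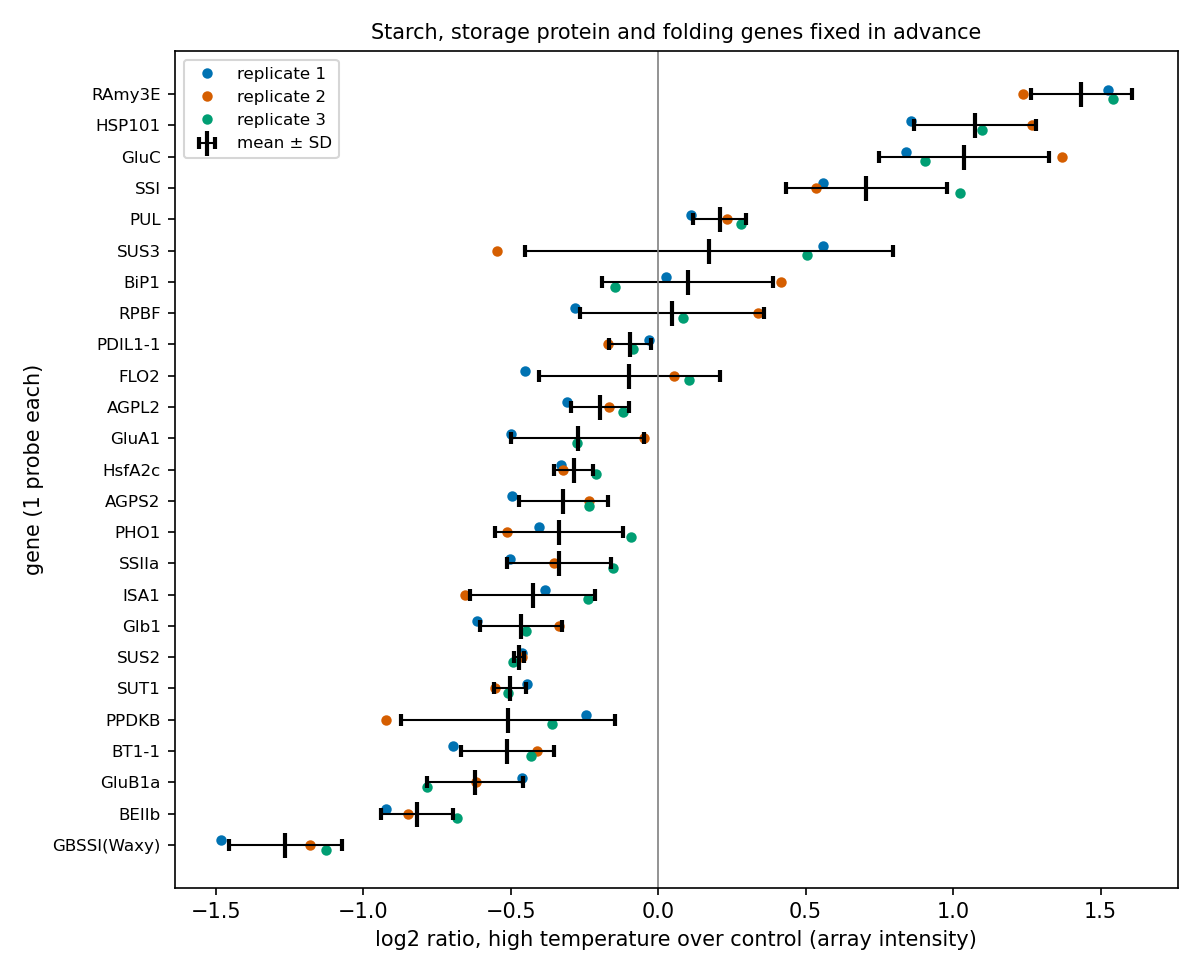
Log2 ratio of high temperature over control for the tested genes that were named in advance for starch, sucrose, storage proteins, heat shock and protein folding. Points are the 3 replicates and black marks with bars are mean ± SD; RAmy3E is highest at 1.43 and GBSSI (Waxy) lowest at -1.26, and the replicates of SUS3, BiP1, RPBF and FLO2 lie on both sides of 0.

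Of 13 prolamin genes 9 fell, none rose and 4 did not pass, and adjusted over the list alone 9 fell and 1 rose. The list's median was -0.82, with an adjusted p of 0.043 by camera, 0.0434 with the slide as a block, and adjusted p = 0.936 with an estimated correlation, in a range over the alternatives of 0.000212 to 0.936. Os05g0328800 was at -1.36 ± 0.87, Os05g0329100 at -1.28 ± 0.85 and Os07g0206400 at -1.23 ± 0.53. The replicates differed in size, with list medians of -1.08, -0.35 and -0.98 in replicates 1, 2 and 3 and of -0.75 and -0.98 on slides 1 and 2. Without replicate 1 the list's adjusted p was 0.0699, and without replicate 3 the adjusted p-values of those 3 genes were 0.109, 0.116 and 0.0517, the highest over their alternatives, the lowest being 0.00146, 0.00168 and 0.000543. With the slide as a block Os05g0328800 and Os05g0329100 were at 0.0593 and 0.0640. Of 15 genes for glutelins and globulin, the storage proteins of the other kind of protein body, 3 rose, 4 fell and 8 did not pass (3 and 5 adjusted over the list alone; list adjusted p of 0.855, median -0.03, mean 0.01). GluC (Os02g0453600) rose by 1.04 ± 0.29, whereas GluB1a (Os02g0249800), whose probe is listed under 2 loci, fell by 0.62 ± 0.16. The globulin gene Glb1 (Os05g0499100) was at -0.47 ± 0.14 (adjusted p = 0.00572; 0.0502 without replicate 3, in a range of 0.000264 to 0.0502) and GluA1 (Os01g0762500) at -0.27 ± 0.23 (adjusted p = 0.0629, negative on 5 of 6 arrays), or -0.39 without replicate 2 (adjusted p = 0.0155, in a range of 0.0155 to 0.215). Storage protein genes have near-identical copies, so a probe's value can come from more than 1 of them. Of 34 genes of the seed allergen and amylase inhibitor family 6 rose, 10 fell and 18 did not pass (6 and 11 adjusted over the list alone; list adjusted p of 0.616). Os10g0552600, of this family, fell by 2.15 ± 0.22.

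The list of cell cycle and histone genes was lower, with 21 of 49 genes falling, 3 rising and 25 not passing, and the same 21 and 3 adjusted over the list alone. Histones made up 47 of these 49 genes and all of the calls. The median was -0.28, with an adjusted p of 0.00428 by camera, 0.00383 with the slide as a block, and adjusted p = 0.936 with an estimated correlation, in a range over the alternatives of 3.7e-05 to 0.936. After Os05g0461400, the histone H3 gene Os12g0415800 was at -0.90 ± 0.22, the histone H4 gene Os02g0684500 at -0.90 ± 0.36 and the histone H1 gene Os03g0799000 at -0.84 ± 0.13. The list's median was -0.07 in replicate 1, against -0.40 and -0.34 in replicates 2 and 3, and -0.32 and -0.34 on slides 1 and 2.

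None of the 3 lists of markers of other grain tissues passed. Of 67 genes listed for the green pericarp 28 rose, 12 fell and 27 did not pass (29 and 12 adjusted over the list alone; list adjusted p of 0.10). The list took in 22 genes with a plastocyanin-like domain, which is not limited to photosynthesis proteins, and of these 6 rose and 5 fell. Of the other 45 genes 22 rose, 7 fell and 16 did not pass. The chlorophyll-binding protein genes Os01g0720500 and Os01g0600900 rose by 1.55 ± 0.24 and 1.53 ± 0.16, and the plastocyanin-like gene Os02g0720100 fell by 1.83 ± 0.20. Of 28 embryo and aleurone markers 7 rose, none fell and 21 did not pass (5 rose and none fell adjusted over the list alone; list adjusted p of 0.459). Their median was -0.24 in replicate 1, 0.43 in replicate 2 and 0.10 in replicate 3, so replicate 2, in which the prolamin median was nearest 0, also had the highest embryo and aleurone median. The dehydrin gene Os11g0453900 (RAB16D) rose by 1.95 ± 0.81 and the late embryogenesis abundant gene Os06g0110200 by 1.97 ± 1.12, the latter with an adjusted p of 0.0669 without replicate 3 and 0.0519 with the slide as a block, in a range of 0.00132 to 0.0669. Of 2 measured nucellus markers 1 rose, also adjusted over the list alone, the nucellin-like Os11g0183900 at 0.96 ± 0.04, whose other probe was at 0.05 (list adjusted p of 0.308).

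**Figure D3:**
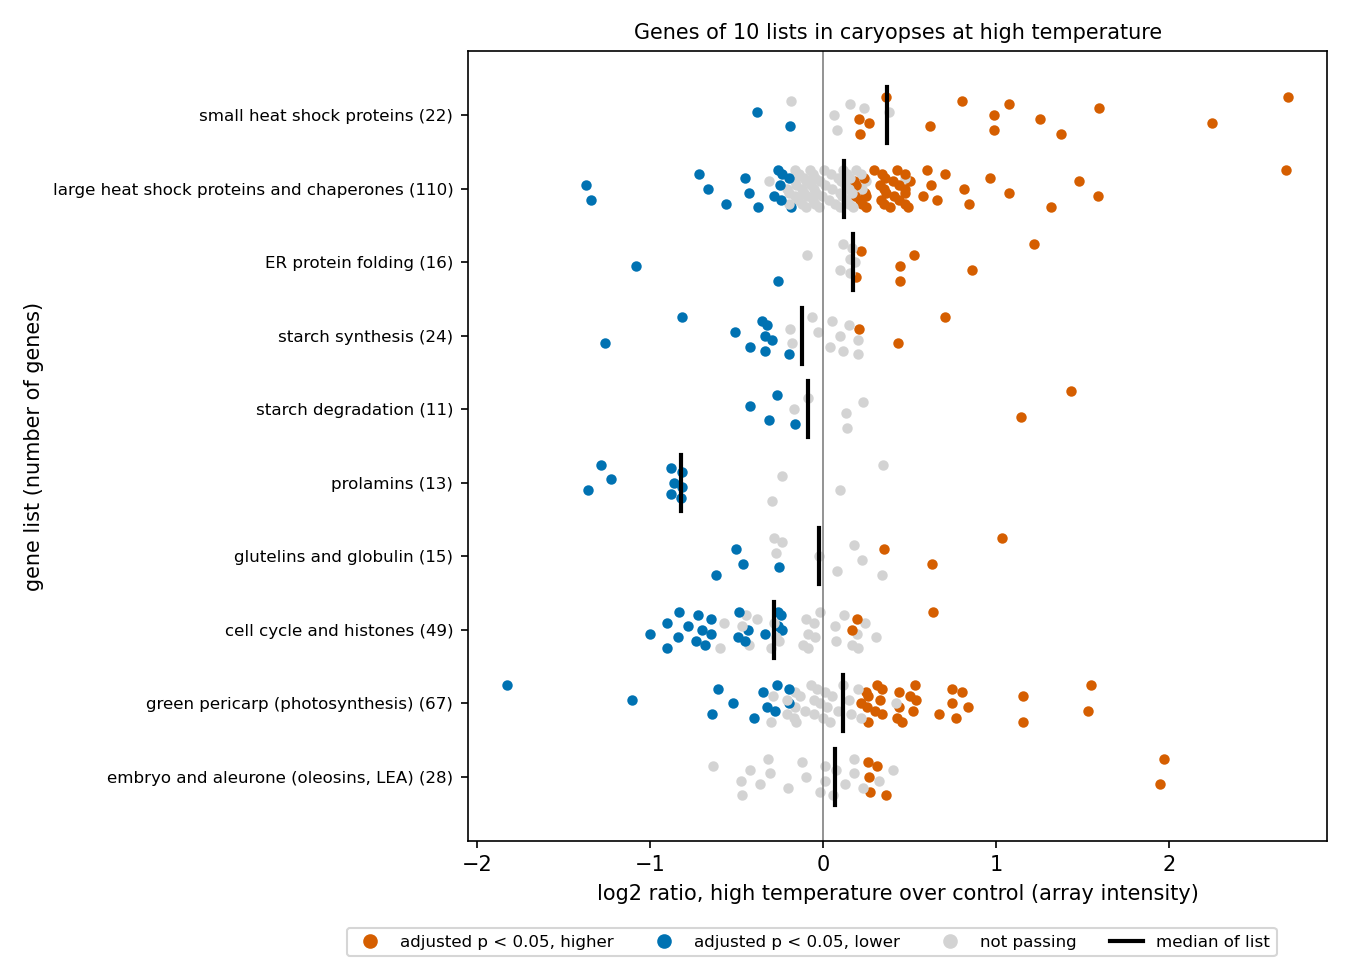
Log2 ratio of high temperature over control for each measured gene of 10 lists, 1 probe per gene. Orange points rose and blue points fell past an adjusted p of 0.05, grey points did not pass, and black bars are list medians, which run from 0.37 for small heat shock proteins to -0.82 for prolamins.

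Central metabolism and translation lists held calls in both directions. Of 62 glycolysis genes 17 rose, 10 fell and 35 did not pass (14 and 8 adjusted over the list alone; list adjusted p of 0.542). The phosphoglycerate kinase gene Os06g0668200 rose by 0.86 ± 0.09 and the enolase gene Os06g0136600 fell by 0.74 ± 0.06. PPDKB (Os05g0405000), for pyruvate orthophosphate dikinase, was at -0.51 ± 0.36 (adjusted p = 0.032; 0.0961 without replicate 3 and 0.0959 with the slide as a block, in a range of 0.0106 to 0.0961). Of 61 citric acid cycle and respiration genes 11 rose, 17 fell and 33 did not pass (10 and 16 adjusted over the list alone; list adjusted p of 0.459), and the alternative oxidase gene Os04g0600200 rose by 0.75 ± 0.30. Of 48 aminoacyl-tRNA synthetase genes 4 rose, 16 fell and 28 did not pass (4 and 15 adjusted over the list alone; list adjusted p of 0.0914), with the glutamyl-tRNA synthetase gene Os01g0271200 at -0.62 ± 0.10. Of 228 ribosomal protein genes 27 rose, 29 fell and 172 did not pass (24 and 21 adjusted over the list alone; list adjusted p of 0.459), and their median was 0.15 in replicate 1 against -0.13 in replicates 2 and 3.

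Of 84 antioxidant enzyme genes 23 rose, 16 fell and 45 did not pass (25 and 16 adjusted over the list alone; list adjusted p of 0.459). The superoxide dismutase gene Os03g0219200 rose by 1.21 ± 0.14, the peroxisomal ascorbate peroxidase gene Os04g0223300 by 1.05 ± 0.16 and the glutathione S-transferase gene Os10g0481300 by 1.38 ± 0.14. Of 92 protease genes 30 rose, 17 fell and 45 did not pass (30 and 18 adjusted over the list alone; list adjusted p of 0.459). Of 28 lipid transfer protein genes 6 rose, 7 fell and 15 did not pass, with the same calls adjusted over the list alone (list adjusted p of 0.917), and Os08g0131200 rose by 2.00 ± 0.28. Of 10 genes of abscisic acid and gibberellin metabolism 2 rose, 1 fell and 7 did not pass, also adjusted over the list alone (list adjusted p of 0.917; median -0.12, mean 0.02). ABA8ox2 (Os08g0472800), which inactivates abscisic acid, rose by 0.92 ± 0.08. Of 8 endosperm transcription factors 3 rose and 5 did not pass, with the same 3 adjusted over the list alone (list adjusted p of 0.459). These were NAC26 at 0.52 ± 0.38 and NAC20 at 0.47 ± 0.35, each positive on 5 of 6 arrays, and NF-YC12 at 0.42 ± 0.22, positive on 4 of 6. Without replicate 3 their adjusted p-values were 0.158, 0.16 and 0.0711. Without replicate 2 NAC26 and NAC20 were smaller, at 0.35 and 0.30 (adjusted p = 0.0686 and 0.0722), and with the slide as a block their adjusted p-values were 0.0901 and 0.0982. The ranges over the alternatives of NAC26, NAC20 and NF-YC12 were 0.00784 to 0.176, 0.00853 to 0.241 and 0.00208 to 0.718. RPBF was at 0.05 ± 0.31 (adjusted p = 0.77, positive on 3 of 6 arrays) and FLO2 at -0.10 ± 0.31 (adjusted p = 0.535, negative on 4 of 6).

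No list passed camera with an estimated correlation between genes, so its list calls rest on the preset value. By fry, which presets no correlation, small heat shock proteins passed (limma adjusted p = 0.0270), while prolamins (0.215) and histones (0.116) did not. Temperature and age at harvest changed together and could not be separated in any of these comparisons.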

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

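The tests of the endosperm share, of both harvest-stage explanations, of spike-in centring, of the wider division gene set, of matching bases between prolamin probes and of the defence genes without transcription factors were chosen after the results were seen.

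PDIL1-1, a disulfide isomerase gene named in advance, had opposite signs in the 2 dye orientations, with a mean of 0.11 with high temperature in Cy5 and -0.30 with it in Cy3. Its dye effect was 0.201 on the log2 scale (limma adjusted p = 4.33e-05), and its mean over both orientations did not pass. Across all tested probes a dye effect passed for 15288, none of it 2-fold and with a median size of 0.0612, and 49 called probes had opposite signs by orientation on all 6 arrays. Outside the main comparison, 7.84% of the probes named for miRNAs (40 of 510) were well above background in both channels of all 6 arrays. The same held for 0 of 153 negative control spots and 0 of 12 artificial sequence probes. By their names, some of the 40 probes target the mature miRNA and others a 5' or 3' sequence. A limma fit of these 40 pooled their variances fully (infinite prior degrees of freedom), so its p-values are not sound and no calls are given.

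Of 13 prolamin genes 9 fell (list adjusted p = 0.936 with an estimated correlation), while glutelins did not move as a list. If several probes had read 1 transcript, most would share long stretches, and although the largest group of the 9 falling probes joined by 30 shared bases held 2, that bound passes over copies with scattered mismatches: 6 of the 9 joined at 40 or more matching bases of 60, the closest pair at 48, which leaves shared reading open. A smaller share of endosperm RNA would lower both lists alike. The prolamin median lay below the glutelin median (difference -0.751 ± 0.389, n = 3) by more than the SD of 0.457 between glutelin genes. In replicates 1, 2 and 3, 0, 2 and 0 of 15 such genes were as low as the prolamin median. These values lean against a smaller share as the whole cause, but the difference was within 2 SD between replicates of 0. That 2 SD bar was the first set for this test and was loosened after the value was seen, so a smaller share stays open. An earlier stage as the only difference might raise histone genes. The median of the list of cell cycle and histone genes was -0.272 ± 0.179 (n = 3), less than 2 SD below 0, which does not decide. The temperature itself and the age at harvest also remain open and cannot be told apart.

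Of 47 histone genes 21 fell, 3 rose and 23 did not pass (adjusted p = 0.936 by camera with an estimated correlation for the whole list of cell cycle and histone genes). A later stage as the only difference might raise prolamins, whose list median was -0.803 ± 0.395 over replicates (n = 3), only just past 2 SD below 0. How prolamin transcripts change with stage at this age was not measured here, so this does not decide. With spike-in centring the list median was -0.359 ± 0.326, farther from 0 than the -0.272 ± 0.179 with the main centring. On average, centring on the bulk of probes thus did not enlarge the fall. Both medians were within 2 SD of 0 and the spike-in shift itself varied between replicates (0.0865 ± 0.157). The test could therefore not tell centring apart from a change. The fall may be one of histones alone: the 2 other members of the list, PCNA and an MCM3 homolog, had a median of 0.16 ± 0.193, neither passing, and a wider set of 151 genes with words of replication and division in their descriptions, chosen and then corrected after such results were seen, was at -0.0461 ± 0.0877 with 26 higher and 33 lower. That set took in genes of other kinds, such as 2 for fatty acid condensing enzymes and a Cdc73 factor, so it and so few list members leave it open.

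Of the 10 largest rises, 3 were thionin-type genes on chromosome 6, whereas the other 2 tested, Os02g0629800 and Os03g0130300, were at 0.83 ± 0.46 (limma adjusted p = 0.0140) and -0.10 ± 0.15 (limma adjusted p = 0.312). The probes of the 3 shared at most 12 bases in a row and matched at 19 to 21 of 60 bases, so they were not near-identical. Probes from different stretches could still read 1 transcript or similar copies. No transcripts were compared with the probes, so shared reading stays open. A general rise of defence genes was not seen over 112 other genes with pathogenesis-related descriptions, of which 26 rose and 29 fell (limma's camera, adjusted p = 0.726 for this 1 list, which equals its unadjusted value). Their median was -0.0041, but 32 of them were annotated as transcription factors, and of the other 80, with a median of 0.0322, 23 rose and 19 fell (limma's camera, adjusted p = 0.833, again for 1 list), so a rise of part of them stays open. Chitinase genes Os08g0518800, Os01g0660200 and Os01g0860500, picked after their values were seen, were at 2.18 ± 0.46, 2.13 ± 0.27 and 2.07 ± 0.38, whereas the class III chitinase gene Os10g0416800 was at -2.21 ± 0.57, and temperature and age at harvest stay open as untested.

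Over the 10 splits of the 6 RNAs into 3 and 3, too few for a share under 0.05, the real split called 13712 probes in the separate-channel fit and the highest other split 0, as large a result in 1 split; at 2-fold the values were 575 and 0, again 1 split. For gene lists the real split called 3 and the highest other 8, and 7 of 10 splits called at least as many. Every other split mixed RNAs of both conditions on each side. A difference between the conditions would then widen the spread within a side, which lowers probe counts, and stay in part between the sides. The other splits thus do not show what would be called with no difference between the conditions, for probes or for lists.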

How the results depend on the processing

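Centring on spike-in probes was chosen after seeing the data. None of the 116 called named genes changed sign under any setting, and 86 stayed past the threshold under every setting that tested them. Most were picked for being called with large ratios, which favours a stable sign. Of all 13020 called probes, 60 changed sign with control in Cy5 only and 63 with high temperature in Cy5 only. Among the named genes 25, 9 and 6 lost the call without replicate 3, 2 and 1. For values that changed below, the cause was not tested, except that fewer replicates or a used degree of freedom lower power by construction. Changed probes numbered 7573 with the slide as a block and 5008 to 11481 with 1 replicate left out, the lowest without replicate 3. At least 2-fold changes numbered 1196 with the processed signals and 1196 with the series matrix, 720 higher and 476 lower in both. Replicate numbers mark no shared batch in the labels, and deviations of same-numbered RNAs correlated at 0.03, -0.36 and 0.39; the separate-channel fit gave 12977 changed probes with the replicate block and 13712 with no replicate block. Shifted lists numbered 0 by camera with an estimated correlation (0 at an unadjusted p under 0.05), 5 with fry and 3 to 5 with 1 replicate left out. The prolamin list's adjusted p was 0.0653 with median centring, 0.0966 with the replicate as a random block, 0.936 with an estimated correlation, 0.215 with fry and 0.000212 to 0.0699 with 1 replicate left out, the highest without replicate 1. Small heat shock proteins and the cell cycle and histone list were at 0.936 with an estimated correlation, while with fry they were at 0.0270 and 0.116. Lists that did not pass with the main settings passed as follows: endoplasmic reticulum folding (0.0337 without a filter, 0.0279 with fry), nucellus markers (0.0373 with the random block, 0.0270 with fry), large heat shock proteins (0.00192 with fry), starch degradation with fry, and ribosomal proteins, tRNA synthetases and embryo and aleurone markers without replicate 1 (values below). Starch degradation turned to a rise without a filter (0.608), with the random block (0.238), with the mean over probes (0.929), with fry (0.0270), with spike-in centring (0.435) and within its left-out range of 0.761 to 0.986. Abscisic acid and gibberellin genes turned with the random block (0.966), the mean over probes (0.991), fry (0.210) and spike-in centring (0.977), and left-out values were 0.689 to 0.939. Glutelins turned with median centring (0.923) and heat shock factors with the random block (0.972). Left-out ranges were 0.000262 to 0.912 for ribosomal proteins, 0.00951 to 0.362 for tRNA synthetases, 0.00951 to 0.689 for embryo and aleurone markers, in each case lowest without replicate 1, and 0.569 to 0.912 for lipid transfer proteins. Of genes not called with the main settings, BiP1 was at -0.11 with control in Cy5 only, RPBF at -0.11 and PDIL1-1 at 0.11 with high temperature in Cy5 only, and RPBF at -0.039 with spike-in centring. Leaving out 1 replicate gave SUS3 -0.021 to 0.53, FLO2 -0.20 to 0.079, BiP1 -0.060 to 0.22 and RPBF -0.098 to 0.21. Dim probes limit folds: the signal over background sets only a bound for genes not well above it.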

Other observations

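The family tests were chosen after the gene list results were seen. Grouping genes by the family named in their description, 149 families of at least 10 genes were tested. In limma, 0 passed camera with a preset correlation (14 at an unadjusted p under 0.05). By a one-sided Fisher's exact test against all tested genes, 3 held more falls than the rest: mitochondrial substrate carriers, which move metabolites across the inner membrane (17 of 32 fell, 2 rose, adjusted p = 0.0140), genes annotated with a TGF-beta receptor-type extracellular region (18 of 35 fell, 5 rose, adjusted p = 0.0140) and alpha/beta hydrolases (14 of 25 fell, 2 rose, adjusted p = 0.0154). With an estimated correlation all 3 were at an adjusted p of 0.974 by camera. None held more rises. Genes of a family are not independent.

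Loci next to each other on a chromosome may change together slightly. Over 19599 neighbouring pairs with different descriptions the log2 ratios correlated with r = 0.0436 across genes, above the highest of 1000 shuffles of the loci (0.0219), and at 0.0421, 0.0441 and 0.0437 in replicates 1, 2 and 3. The relation is weak, and shared function or shared probe sequence between neighbours was not excluded.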
